A study of Mus musculus with 16 samples.

How the data were processed

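RNA-seq was run on liver tumors and nontumor liver of 8 mice, giving 16 samples in 4 groups of 4. Per the labels, polyadenylated RNA was extracted with Trizol and sequenced on an Illumina instrument. Per the submitters' processing notes, reads were checked with FastQC, aligned with HISAT2 to mm10, handled with SAMtools and counted with featureCounts, with no versions given. The deposited table holds TPM values for 20601 genes in 16 columns. The step from counts to TPM, the gene annotation and the rule that chose the listed genes were not stated by the submitters. The 8 nontumor columns carry the letter P where the sample titles carry N, and they were matched to the samples by diet letters and number. No mitochondrially encoded gene is listed (0), so such genes were not analysed here.

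Because TPM values of a library are whole reads times a constant per gene, read numbers were recovered from the steps between a gene's values, and 20600 of 20601 genes were solved within 0.001 reads of whole numbers. On simulated data 100% of 3880 genes were solved and 99.79% equalled the truth. The recovered reads served only to give the depth over the listed genes (3.42 to 12.89, in units of 1e6 reads), to thin libraries and to run an alternative fit. The listed values summed to 49.96% to 88.45% of the TPM total in 15 libraries and to 7.38% in ND nontumor 4. No library was dropped. No 2 libraries of the same group were copies of each other, with a chi-square per degree of freedom of 12.2 or more for every pair within a group.

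The test fixed before any value was seen was limma with a variance trend on log2(TPM + 1), with equal weights, all 16 libraries in 1 fit and no block. Genes with TPM of at least 1 in at least 4 of 16 libraries were tested (13432). The contrasts were tumor against nontumor on each diet, KD against ND in each tissue, and the interaction. The Benjamini-Hochberg adjusted p threshold was 0.05. Once values were seen, median-of-ratios factors over the 11798 genes above 0 in all 16 libraries were found to shift the median gene by more than 0.1 log2 units in most comparisons, and the factor of ND nontumor 4 was 0.128. The same fit was therefore run on TPM divided by these factors, and single genes and gene lists are given from it beside counts on the deposited scale. On simulated 2-fold and 4-fold changes added to the ND libraries, the deposited scale recovered 11% and 67%, with 35 unchanged genes called, and the rescaled values recovered 54% and 99%, with 10 unchanged genes called. Even on rescaled values, changes of 2-fold or smaller are often missed at n = 4. The samples came from 8 mice, and the labels do not say that equal numbers mark 1 mouse, so no block was used.

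Of 48 gene lists written before any value was seen, 45 had enough tested members and were compared with all other tested genes by limma's camera with a preset correlation of 0.01, then with a correlation estimated from the data. After rescaling 27 lists passed for tumor against nontumor on ND, 28 on KD, 16 for the diets in tumor, 17 in nontumor liver and 18 for the interaction, and on the deposited scale 27, 28, 19, 20 and 19. P-values were also adjusted over each list alone. In simulations camera called a list of changed genes and 0 of 20 random lists, which do not test correlation. A score of fatty acid degradation was the mean log2(TPM + 1) of the 43 tested members, compared by exact permutation (70 assignments of 4 against 4 libraries).

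Genes were named by a rule fixed beforehand: the 8 largest rises and 8 largest falls per comparison among genes that passed, with groups that do not overlap and a mean of at least 5 TPM in the higher group; up to 4 members of each list; 21 set genes of the model and of fat, ketone and sugar metabolism; and for the interaction the 6 smallest p-values per direction. Predicted and clone names were excluded, and 2 genes that met the rule are counted but not reported here. Gene positions and exon sequences came from GENCODE M21 for GRCm38, in which 19991 symbols had 1 match and 579 none.

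Transcript length and GC trends were removed per library with lowess curves (span 0.3, 3 iterations) fitted in turn over 5 cycles, for 13129 genes (97.7%). A first form with a single pass left a length trend in simulated data (Spearman's rho 0.32) and was replaced, and its counts are kept as an alternative. With 200 genes changed 4-fold in simulated data, both forms recovered 96%, with 19 unchanged genes called by the first and 14 by the second, against 2740 without adjustment. Chance was assessed by splitting the same libraries into groups of the same sizes in all 35 ways, or 100 ways for the interaction.

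Alternatives were a pseudocount of 0.1, no filter, rescaling, the listed genes scaled to 1 common sum, only the groups compared, sample weights, the replicate number as a fixed or random block, a log2 fold change of at least 1, voom on the recovered reads, the length and GC adjustment, and each library left out in turn. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.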

Results

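Gene expression was measured by RNA-seq in liver tumors and nontumor liver of mice carrying a hydrodynamically induced hepatocellular carcinoma. In this model, plasmids for human N-Ras (19 µg) and human c-Myc (1 µg) were delivered to each mouse with a Sleeping Beauty transposase (2 µg), an enzyme that integrates the transgenes into hepatocyte DNA. From week 4 the mice received a ketogenic diet (KD; 0.1% carbohydrate, 89.5% fat, 10.4% protein) or a normal diet (ND) for 4 weeks, and tissue was taken at week 8. The 16 samples came from 8 mice and formed 4 groups of 4, namely KD nontumor, KD tumor, ND nontumor and ND tumor. Both tissues came from the same 8 mice, so the 16 samples are not all independent, and p-values measure the spread between these samples. The series title refers to FAD subtypes of this cancer, and FAD was taken to stand for fatty acid degradation. The comparisons ask how tumors differed from nontumor liver on each diet, how the diets differed within each tissue, and whether the diet effect differed between the tissues.

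Expression was given as TPM for 20601 genes. The listed genes held 66.79% to 88.45% of each library's TPM total in KD nontumor, 77.05% to 79.93% in KD tumor and 49.96% to 66.48% in ND tumor. In ND nontumor the share was 73.36% to 84.29% in 3 libraries and 7.38% in replicate 4. Whole reads recovered from the values gave the depth over the listed genes, in units of 1e6 reads. It was 5.46 to 10.53 in KD nontumor, 8.06 to 12.89 in KD tumor, 6.58 to 9.21 in ND tumor and 3.42 to 8.31 in ND nontumor, with ND nontumor 4 the lowest. All 16 libraries had Xist at or below 0.17 TPM and the Y-linked Ddx3y at 2.27 to 42.4 TPM, a male pattern. After rescaling by the median of ratios, the first principal component held 46.8% of the variance and separated all tumor (22.9 to 59.7) from all nontumor libraries (-65.2 to -27.3). The second held 15.4% and separated ND tumor (17.5 to 45.1) from KD tumor (-41.6 to -20.6).

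**Figure D1:**
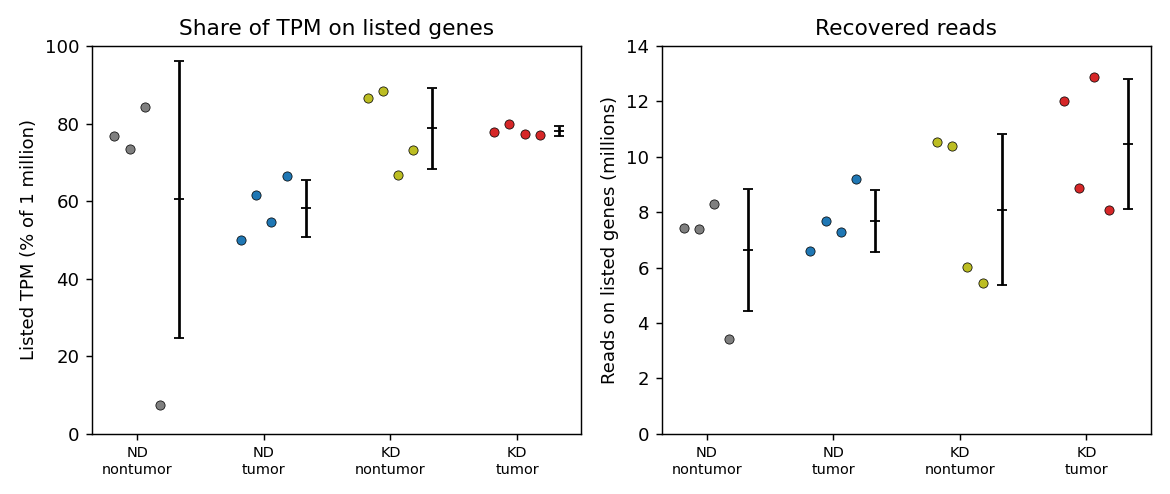
Share of the TPM total held by the listed genes (%, vertical axis) in each of the 16 libraries, by group, with the group mean and SD. ND nontumor replicate 4 lies at 7.38%, and the other 15 libraries at 49.96% to 88.45%.

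**Figure D2:**
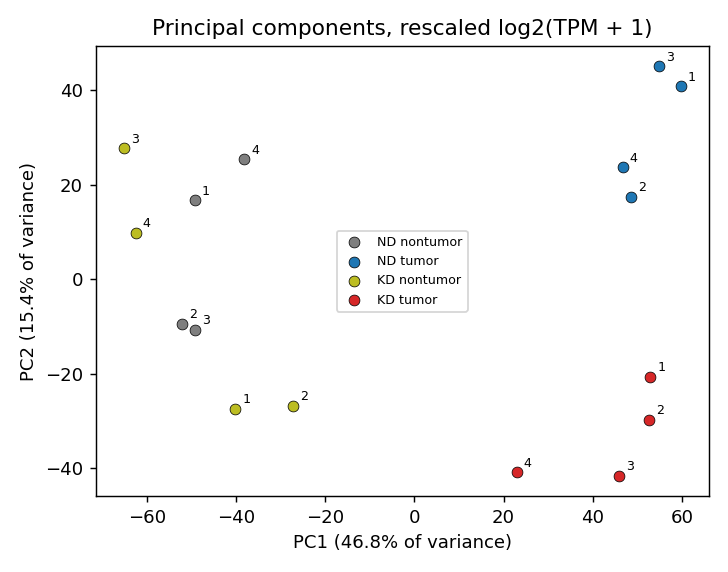
Principal components 1 and 2 of the rescaled log2(TPM + 1) values, in component units, one point per library, numbered by replicate. Tumor libraries lie at 22.9 to 59.7 on component 1 and nontumor libraries at -65.2 to -27.3.

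Rescaling by the median of ratios moved the median log2 fold change of all 13432 tested genes by more than 0.1 in 4 of the 5 comparisons. With deposited values that median was 0.42 for tumor against nontumor on ND, -0.26 on KD, 0.69 for KD against ND in nontumor liver and -0.67 for the interaction. It was 0.00 for KD against ND in tumor. With the listed genes of each library scaled to 1 common sum, the medians in the same order were 0.22, -0.27, 0.1, -0.49 and -0.35. Unequal listed shares therefore did not account for the shift on KD. Counts are therefore given on the deposited scale and after rescaling, and the values of single genes and gene lists are those after rescaling, relative to the median gene. Each is a log2 fold change ± SE on the log2(TPM + 1) scale from limma, with n = 4 per group and a Benjamini-Hochberg adjusted p threshold of 0.05. The added 1 makes it smaller than the true change for low genes. Levels are rescaled TPM ± SD. Members of the major urinary protein, Cyp2c, Cyp4a, Gstm and globin families share sequence, so the split of reads between close copies is uncertain.

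Tumors on the normal diet had lower levels of Mup11, Cyp2c54 and Cyp4a14 than nontumor liver, and higher levels of Cyp2a4 and Psrc1. Mup11 (chromosome 4, 60658466 to 60662411), a major urinary protein secreted by male hepatocytes, went from 5463 ± 2383 TPM in nontumor liver to 8.91 ± 2.51 TPM in tumor (-9.02 ± 0.35, adjusted p = 1.92e-10). Cyp2c54 (-8.40 ± 0.46, adjusted p = 1.13e-08) and Cyp2c37 (-7.85 ± 0.68, adjusted p = 7.4e-07), cytochrome P450 enzymes of drug and lipid oxidation, fell with it. Cyp4a14, a microsomal fatty acid hydroxylase, fell too (-6.87 ± 0.65, adjusted p = 1.87e-06). Under the rule for naming genes, the largest rises were those of Cyp2a4 (6.63 ± 0.90, adjusted p = 5.18e-05), a female-biased steroid hydroxylase, and Psrc1 (6.43 ± 0.44, adjusted p = 6.34e-08), which encodes a spindle protein. Next were Ly6d (6.29 ± 0.90, adjusted p = 8.5e-05) and the iron-binding acute phase protein Lcn2 (6.09 ± 0.88, adjusted p = 8.8e-05). The liver tumor markers Afp (3.65 ± 0.83, adjusted p = 0.00348) and Gpc3 (3.42 ± 0.52, adjusted p = 0.000142) rose. Mouse Nras (0.29 ± 0.15, adjusted p = 0.17) and Myc (-0.06 ± 0.40, adjusted p = 0.93) did not pass; the delivered genes are human, and whether their reads count toward the mouse genes was not tested.

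A total of 1418 genes were differentially expressed between tumor and nontumor liver on ND on the deposited scale, of which 1094 (77.2%) were higher and 324 lower in tumor. After rescaling the number was 3852, of which 1953 (50.7%) were higher and 1899 lower. Both scales called 1324 genes in the same direction and none in opposite directions. In 27.5% of tested genes the 4 tumor values did not overlap the 4 nontumor values, where chance gives 2.9%. Without ND nontumor 4 the deposited scale gave 3067 genes (1227 higher, 1840 lower) and the rescaled values 3672 (1856 higher, 1816 lower). Of the 167 named genes that passed in this comparison, 122 also passed on the deposited scale.

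In the fatty acid degradation list, 21 of 43 tested members fell, 5 rose and 17 did not pass. With p adjusted over the list alone, written below as within the list, 27 fell and 5 rose (median -0.94). The list as a whole was lower than other genes by limma's camera test (adjusted p = 2.87e-07), and adjusted p = 0.317 with an estimated correlation between members. Cyp4a14, Cyp4a10 (-5.78 ± 0.57) and Cyp4a12a (-5.36 ± 0.58) fell most. The medium-chain acyl-CoA dehydrogenase Acadm (chromosome 3, 153922357 to 153944632) fell from 152 ± 30 TPM to 58.4 ± 12.4 TPM (-1.37 ± 0.21). Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, missed the threshold (-0.58 ± 0.21, adjusted p = 0.0503). Of 28 target genes of PPAR alpha, the nuclear receptor of fasting fat oxidation, 17 fell and 3 rose (19 and 5 within the list; adjusted p = 1.24e-05, and adjusted p = 0.317 with an estimated correlation). Examples were Acot1 (-3.45 ± 0.28) and Angptl4 (-2.31 ± 0.28). The hormone gene Fgf21 rose (1.51 ± 0.27). Among 9 ketone body genes 1 fell, with 1 within the list. The list did not pass (median 0.10, mean -0.09, adjusted p = 0.854). Peroxisome biogenesis genes were lower (7 of 16 fell, 7 within the list; adjusted p = 0.00252, and adjusted p = 0.317 with an estimated correlation), Pex11a among them (-1.29 ± 0.31).

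Bile acid genes were lower as a group, with 14 of 17 falling (14 within the list; median -1.87, adjusted p = 1.85e-11, and adjusted p = 0.148 with an estimated correlation). Cyp8b1, the sterol 12-hydroxylase (-5.76 ± 0.37), Cyp7b1 (-5.75 ± 0.45) and the uptake carrier Slco1a1 (-4.22 ± 0.28) led them. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 3.23 ± 0.90 TPM in nontumor liver and was listed at 0 in 3 of the 4 tumors. Of 24 cholesterol synthesis genes 13 rose and 2 fell (15 and 2 within the list; adjusted p = 0.000132, and adjusted p = 0.472 with an estimated correlation). Examples were Sqle (2.10 ± 0.42) and Dhcr7 (2.07 ± 0.30). Of 38 genes of the urea cycle and amino acid catabolism 23 fell and 1 rose (26 and 1 within the list; adjusted p = 2.54e-10, and adjusted p = 0.314 with an estimated correlation). Oat (-4.97 ± 0.43) and Tat (-3.72 ± 0.51) were among them. Of 13 gluconeogenesis genes 9 fell and 1 rose (9 and 1 within the list; adjusted p = 0.00188, and adjusted p = 0.216 with an estimated correlation). Pck1 was at 386 ± 66 TPM in tumor and 4137 ± 636 TPM in nontumor liver. The tricarboxylic acid cycle was lower (5 of 21 fell, 5 within the list; median -0.40, adjusted p = 0.00652, and adjusted p = 0.51 with an estimated correlation). So was oxidative phosphorylation (7 of 42 fell, 4 within the list; median -0.51, adjusted p = 0.00134, and adjusted p = 0.624 with an estimated correlation). Glycolysis (8 rose, 3 fell of 25; adjusted p = 0.0658), lipogenesis (6 rose, 4 fell of 22; median -0.14, mean 0.15, adjusted p = 0.758) and glycogen metabolism (4 rose, 3 fell of 13; adjusted p = 0.642) did not pass as lists. Within the list the counts were 8 and 3, 6 and 4, and 4 and 4. Gpi1 (2.24 ± 0.29), Scd2 (2.99 ± 0.51) and Pkm (1.65 ± 0.38), the pyruvate kinase of growing cells, rose among their members.

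All 23 tested male-biased genes fell (23 within the list; median -5.26, adjusted p = 5.38e-26, and adjusted p = 0.0594 with an estimated correlation). Of 10 female-biased genes 6 rose and 1 fell (8 and 1 within the list; adjusted p = 0.00177, and adjusted p = 0.3 with an estimated correlation). Genes of pericentral hepatocytes, those around the central vein, fell in 18 of 21 cases (21 within the list; median -2.77, adjusted p = 6.99e-17). This was the only list of the 45 tested to pass with an estimated correlation after rescaling, in any comparison (adjusted p = 0.044). Cyp1a2 (-5.79 ± 0.51) and Rgn (-5.01 ± 0.42) were examples. Periportal genes fell in 9 of 19 cases and rose in 4 (10 and 4 within the list; adjusted p = 0.0183, and adjusted p = 0.51 with an estimated correlation). Of 41 P450 and drug metabolism genes 31 fell and 3 rose (33 and 3 within the list; adjusted p = 7.25e-16, and adjusted p = 0.148 with an estimated correlation). Hepatocyte transcription factors fell in 10 of 18 cases and rose in 2 (10 and 2 within the list; adjusted p = 0.00188, and adjusted p = 0.3 with an estimated correlation). Examples were Nr1i3 (-2.56 ± 0.27) and the bile acid receptor gene Nr1h4 (-1.51 ± 0.28).

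Of 28 markers of liver cancer and fetal liver 17 rose and 2 fell (17 and 4 within the list; adjusted p = 7.58e-06, and adjusted p = 0.317 with an estimated correlation). Mitotic genes rose in 18 of 29 cases and fell in 1 (19 and 1 within the list; adjusted p = 7.7e-07, and adjusted p = 0.317 with an estimated correlation). Mki67 (1.78 ± 0.39) and Ube2c (2.17 ± 0.45) were among them. Ribosomal protein genes rose in 34 of 56 cases (41 within the list; median 1.00, adjusted p = 1.88e-11, and adjusted p = 0.472 with an estimated correlation). MYC target genes rose in 13 of 40 cases and fell in 3 (14 and 3 within the list; adjusted p = 0.0183, and adjusted p = 0.544 with an estimated correlation). Genes induced by RAS and ERK signalling rose in 12 of 21 (14 within the list; adjusted p = 0.000399, and adjusted p = 0.317 with an estimated correlation). Examples were the feedback phosphatase Dusp5 (2.79 ± 0.47) and Etv4 (2.19 ± 0.40). The integrated stress response list, which holds amino acid synthesis genes driven by ATF4, rose in 14 of 25 members and fell in 2 (15 and 2 within the list; adjusted p = 2.24e-05, and adjusted p = 0.148 with an estimated correlation). The serine synthesis genes Phgdh (4.19 ± 0.49) and Psat1 (3.89 ± 0.42) led it. Genes of the unfolded protein response in the endoplasmic reticulum fell in 8 of 22 cases (10 within the list; adjusted p = 0.000401, and adjusted p = 0.472 with an estimated correlation), Hyou1 by the most (-1.71 ± 0.20). S phase (adjusted p = 0.0765), NRF2 targets (adjusted p = 0.268), hypoxia (adjusted p = 0.276), the acute phase (adjusted p = 0.0658), secreted proteins (adjusted p = 0.146), the clock (adjusted p = 0.0658) and immediate early genes (adjusted p = 0.501) did not pass as lists.

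Markers of resident macrophages (Kupffer cells) fell in 11 of 16 cases and rose in 1 (11 and 1 within the list; adjusted p = 9.97e-06, and adjusted p = 0.148 with an estimated correlation). Clec4f went from 136 ± 17 TPM to 7.21 ± 2.19 TPM (-4.09 ± 0.27). Monocyte and macrophage markers rose in 8 of 25 cases and fell in 3 (9 and 3 within the list; adjusted p = 0.013, and adjusted p = 0.51 with an estimated correlation). Examples were Spp1 (3.06 ± 0.55) and Cd14 (2.92 ± 0.41). T and NK cell markers rose in 7 of 20 cases (8 within the list; adjusted p = 0.0365, and adjusted p = 0.544 with an estimated correlation). Interferon response genes rose in 7 of 38 cases and fell in 1 (7 and 1 within the list; adjusted p = 0.0103, and adjusted p = 0.51 with an estimated correlation). Red blood cell genes fell in 4 of 7 cases (5 within the list; adjusted p = 0.00474, and adjusted p = 0.381 with an estimated correlation). Endothelial markers split, 10 of 25 rising and 9 falling (10 and 9 within the list; adjusted p = 0.896). Clec4g (-2.94 ± 0.32) and Stab2 (-1.97 ± 0.22), markers of liver sinusoids, fell, and the capillary marker Cd34 rose (2.61 ± 0.26). Stellate cell (median -0.09, mean 0.06, adjusted p = 0.895), MHC class II (adjusted p = 0.0765), B cell (adjusted p = 0.146), neutrophil (adjusted p = 0.278), cholangiocyte (adjusted p = 0.0765) and muscle and gut lists (adjusted p = 0.331) did not pass. Of 2 tested genes of fat and exocrine pancreas, too few for a list test, Cfd fell (-3.50 ± 0.82) and Cela1 rose (1.71 ± 0.34). The peroxisome, tricarboxylic acid cycle and T and NK cell lists did not pass on the deposited scale, where glycolysis (adjusted p = 0.0433), the acute phase (adjusted p = 0.0487) and B cells (adjusted p = 0.0487) did, though none did with an estimated correlation. Counted on that scale, the members that fell were 5 in fatty acid degradation (4 rose), 3 among PPAR alpha targets (3 rose), 7 in bile acids, 5 in the urea cycle and amino acid list and 3 in gluconeogenesis (1 rose). They were 17 in P450 and drug metabolism (2 rose), 21 of the male-biased and 12 of the pericentral genes, 3 periportal (3 rose), 1 hepatocyte transcription factor, 7 Kupffer cell (1 rose) and 3 red blood cell genes. None passed in peroxisomes, the tricarboxylic acid cycle, oxidative phosphorylation and the unfolded protein response. Those that rose were 8 in cholesterol synthesis, 7 female-biased genes, 17 cancer and fetal markers (2 fell), 15 mitotic, 9 ribosomal protein, 5 MYC target and 10 RAS and ERK genes. They were 12 in the integrated stress response (1 fell), 5 monocyte and macrophage, 8 T and NK cell and 3 interferon response genes. The mean log2 scores of the 27 lists did not overlap between tumor and nontumor libraries except for oxidative phosphorylation, interferon response and T and NK cells. For oxidative phosphorylation ND nontumor 1 and 4 (6.289 and 6.243) lay within the tumor range (5.843 to 6.429), so the difference rests on ND nontumor 2 and 3 (7.004 and 7.132).

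Tumors on the ketogenic diet also had lower levels of Mup11 and Cyp2c54 than nontumor liver, and higher levels of Ly6d, Lcn2 and Scd1. Mup11 went from 3107 ± 1010 TPM to 46 ± 20 TPM (-6.06 ± 0.35, adjusted p = 4.7e-08). Also falling were Cyp2c54 (-5.92 ± 0.46, adjusted p = 4.13e-07), the fatty acid elongase Elovl3 (-5.60 ± 0.56, adjusted p = 4.71e-06) and Cyp4a14 (-4.89 ± 0.65, adjusted p = 5.76e-05). Ly6d (6.69 ± 0.90, adjusted p = 6.17e-05), Lcn2 (5.99 ± 0.88, adjusted p = 0.000126) and Prtn3, a neutrophil granule protease (4.94 ± 0.29, adjusted p = 4.7e-08), had the largest rises under the naming rule. Scd1 (chromosome 19, 44394455 to 44407879), the stearoyl-CoA desaturase that makes monounsaturated fat, was at 51.4 ± 22.1 TPM in nontumor liver and 453 ± 189 TPM in tumor (3.12 ± 0.39, adjusted p = 3.11e-05). Afp (3.82 ± 0.83, adjusted p = 0.00248) and Gpc3 (3.45 ± 0.52, adjusted p = 0.000154) rose. Nras did not pass (0.18 ± 0.15, adjusted p = 0.392), and mouse Myc fell (-1.11 ± 0.40, adjusted p = 0.0418).

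A total of 1111 genes were differentially expressed between tumor and nontumor liver on KD on the deposited scale, of which 387 (34.8%) were higher and 724 lower in tumor. After rescaling there were 4360, of which 2186 (50.1%) were higher and 2174 lower. Both scales called 1053 genes in the same direction and none in opposite directions, and in 33.1% of tested genes the groups did not overlap (chance 2.9%). The deposited count was 731 without KD nontumor 3, and it was 4451 (1191 higher, 3260 lower) without ND nontumor 4, which enters this fit through the shared estimate of the spread. The rescaled count without ND nontumor 4 was 4413. Of 169 named genes that passed, 102 also passed on the deposited scale.

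The fatty acid degradation list was lower, with 18 of 43 members falling and 6 rising (18 and 6 within the list; median -0.43, adjusted p = 0.0284, and adjusted p = 0.666 with an estimated correlation). Acadm fell (-0.88 ± 0.21), and Cpt1a (0.65 ± 0.21) and Aldh1b1 (3.36 ± 0.58), a mitochondrial aldehyde dehydrogenase, rose. Of 28 PPAR alpha targets 12 fell and 7 rose (13 and 7 within the list; adjusted p = 0.0382, and adjusted p = 0.666 with an estimated correlation). The PPAR alpha score was 6.403 and 6.107 in KD nontumor 1 and 2, 5.221 and 5.637 in KD nontumor 3 and 4, and 5.037 to 5.554 in KD tumors, so this difference rests largely on KD nontumor 1 and 2. Ppara itself fell (-1.28 ± 0.29). Ketone body genes rose in 4 of 9 cases (4 within the list; median 0.78, adjusted p = 0.0318, and adjusted p = 0.399 with an estimated correlation). Bdh1, which interconverts the 2 main ketone bodies, went from 99.5 ± 46.9 TPM to 300 ± 78 TPM (1.68 ± 0.31). Lipogenesis genes rose in 9 of 22 cases and fell in 3 (9 and 3 within the list; adjusted p = 0.0179, and adjusted p = 0.454 with an estimated correlation). Examples were Scd2 (3.68 ± 0.51) and Fads2 (2.08 ± 0.27). Cholesterol synthesis genes rose in 14 of 24 cases and fell in 1 (16 and 2 within the list; adjusted p = 0.000162, and adjusted p = 0.454 with an estimated correlation). Bile acid genes fell in 14 of 17 cases (15 within the list; adjusted p = 1.61e-09, and adjusted p = 0.264 with an estimated correlation). Cyp7a1 was at 2.14 ± 1.5 TPM in tumor and 18.7 ± 3.7 TPM in nontumor liver (-2.74 ± 0.25). Oxidative phosphorylation genes were higher as a list (median 0.41, adjusted p = 0.0319, and adjusted p = 0.835 with an estimated correlation). Of its 42 members 2 rose and 1 fell (0 and 1 within the list). The mean log2 score of the list was 7.395 and 7.292 in KD nontumor 1 and 2, 5.869 and 6.494 in KD nontumor 3 and 4, and 6.899 to 7.441 in KD tumors, so the difference rests on KD nontumor 3 and 4. The tricarboxylic acid cycle (median 0.01, mean 0.03, lower by the test, adjusted p = 0.995), glycolysis (adjusted p = 0.671), glycogen metabolism (median -0.38, mean 0.04, adjusted p = 0.99) and peroxisome biogenesis (adjusted p = 0.0648) did not pass.

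Urea cycle and amino acid genes fell in 24 of 38 cases and rose in 2 (25 and 3 within the list; adjusted p = 1.49e-06, and adjusted p = 0.399 with an estimated correlation). Gluconeogenesis genes fell in 6 of 13 cases and rose in 1 (6 and 1 within the list; adjusted p = 0.0173, and adjusted p = 0.399 with an estimated correlation). P450 and drug metabolism genes fell in 26 of 41 cases and rose in 2 (29 and 3 within the list; adjusted p = 6.58e-10, and adjusted p = 0.371 with an estimated correlation). Male-biased genes fell in 21 of 23 cases (21 within the list; median -3.33, adjusted p = 8.18e-16, and adjusted p = 0.264 with an estimated correlation). Pericentral genes fell in 15 of 21 cases (17 within the list; median -1.70, adjusted p = 1.39e-06, and adjusted p = 0.264 with an estimated correlation), the Wnt inhibitor gene Notum among them (-3.51 ± 0.21). Female-biased genes rose in 6 of 10 cases and fell in 1 (6 and 1 within the list; adjusted p = 0.0437, and adjusted p = 0.454 with an estimated correlation). Hepatocyte transcription factors fell in 10 of 18 cases and rose in 1 (11 and 1 within the list; adjusted p = 0.000162, and adjusted p = 0.264 with an estimated correlation), Nr1i3 by the most (-3.46 ± 0.27). Secreted proteins rose in 11 of 38 cases and fell in 4 (12 and 4 within the list; adjusted p = 0.0146, and adjusted p = 0.674 with an estimated correlation), Apoa4 by 4.49 ± 0.68. Acute phase genes rose in 10 of 22 cases and fell in 2 (10 and 3 within the list; adjusted p = 0.0283, and adjusted p = 0.666 with an estimated correlation). The iron hormone gene Hamp fell (-4.11 ± 0.87). Both list differences rest on KD nontumor 3 and 4. Secreted protein scores were 10.649 and 10.706 in KD nontumor 1 and 2, 9.399 and 10.045 in KD nontumor 3 and 4, and 10.643 to 10.846 in KD tumors. Acute phase scores were 7.094 and 7.311, 5.518 and 5.757, and 6.955 to 7.377 in the same order. Clock genes fell in 6 of 19 cases (6 within the list; adjusted p = 0.0101, and adjusted p = 0.399 with an estimated correlation).

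All 56 ribosomal protein genes rose (56 within the list; median 1.73, adjusted p = 4.05e-26, and adjusted p = 0.395 with an estimated correlation), while 5 passed on the deposited scale. Mitotic genes rose in 15 of 29 cases (21 higher and 1 lower within the list; adjusted p = 4.74e-06, and adjusted p = 0.399 with an estimated correlation). S phase genes rose in 10 of 35 cases and fell in 3 (12 and 3 within the list; adjusted p = 0.0243, and adjusted p = 0.399 with an estimated correlation). MYC targets rose in 20 of 40 cases and fell in 1 (21 and 2 within the list; adjusted p = 2.97e-05, and adjusted p = 0.399 with an estimated correlation). The nucleolar gene Npm1 was an example (2.22 ± 0.36). Cancer and fetal markers rose in 13 of 28 cases and fell in 1 (14 and 2 within the list; adjusted p = 0.000156, and adjusted p = 0.399 with an estimated correlation). RAS and ERK output genes rose in 8 of 21 cases and fell in 1 (9 and 1 within the list; adjusted p = 0.00744, and adjusted p = 0.454 with an estimated correlation). Genes of the integrated stress response rose in 14 of 25 cases and fell in 3 (16 and 3 within the list; adjusted p = 0.000168, and adjusted p = 0.295 with an estimated correlation). Monocyte and macrophage markers rose in 12 of 25 cases (14 within the list; adjusted p = 0.000106, and adjusted p = 0.399 with an estimated correlation). MHC class II genes rose in 6 of 15 cases and fell in 1 (8 and 1 within the list; adjusted p = 0.0254, and adjusted p = 0.599 with an estimated correlation). Neutrophil genes rose in 1 of 10 cases (1 within the list; adjusted p = 0.0254, and adjusted p = 0.513 with an estimated correlation). Their scores were 3.564 and 3.269 in KD nontumor 1 and 2, 1.849 and 2.045 in KD nontumor 3 and 4, and 3.549 to 4.619 in KD tumors, so the difference rests largely on KD nontumor 3 and 4. Kupffer cell markers fell in 8 of 16 cases and rose in 1 (8 and 3 within the list; adjusted p = 0.0166, and adjusted p = 0.399 with an estimated correlation). Collagen gene Col1a1 (2.17 ± 0.48) and the contractile gene Acta2 (2.86 ± 0.40) rose, but the stellate cell list did not pass (adjusted p = 0.352). Of the remaining lists, none passed, among them endothelial cells (adjusted p = 0.799), red blood cells (adjusted p = 0.682), hypoxia (median -0.01, mean 0.02, adjusted p = 0.995) and immediate early genes (median 0.20, mean -0.14, adjusted p = 0.863). The ketone body and oxidative phosphorylation lists did not pass on the deposited scale, where periportal genes (adjusted p = 0.0368) and cholangiocytes (adjusted p = 0.00731) did, though neither did with an estimated correlation. On that scale fewer members passed in most lists. Falls numbered 8 in fatty acid degradation (2 rose), 7 among PPAR alpha targets, 8 in bile acids, 5 in the urea cycle and amino acid list, 3 in gluconeogenesis and 18 in P450 and drug metabolism (2 rose). They numbered 18 of the male-biased and 13 of the pericentral genes, 4 hepatocyte transcription factors, 6 Kupffer cell and 2 clock genes. Rises numbered 3 in lipogenesis (1 fell), 5 female-biased (1 fell), 1 secreted protein (1 fell), 3 acute phase (1 fell), 5 mitotic and 2 S phase genes (3 fell). They numbered 2 MYC targets, 11 cancer and fetal markers (1 fell), 3 RAS and ERK, 4 integrated stress response, 2 monocyte and macrophage and 1 neutrophil gene. No cholesterol synthesis, ketone body, oxidative phosphorylation or MHC class II gene passed. Scores of tumor and nontumor libraries overlapped for 10 of the 28 lists, namely the 5 whose library scores are given above, fatty acid degradation, cholesterol synthesis, female-biased genes, RAS and ERK output and MHC class II.

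The tumor effects on the 2 diets were alike across genes, which are not independent replicates. The log2 fold changes correlated with Pearson's r of 0.731, Spearman's rho of 0.614 and a covariance of 0.588 on the deposited scale, and 0.746, 0.646 and 0.589 after rescaling. The comparisons share no library. After rescaling, 1115 genes were higher in tumor on both diets, where independent lists of that size share 317.8, and 1085 were lower on both, against 307.4. Opposite calls were made for 11 of the genes higher on ND and 7 of those lower on ND.

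Tumors of mice on the ketogenic diet had higher levels of Cpt1a, Acadm and Bdh1 than tumors on the normal diet, and lower levels of Gstm3, Cbr3 and Gstp2. Cpt1a (chromosome 19, 3322334 to 3385733) was at 115 ± 32 TPM in KD tumors and 41.3 ± 3.4 TPM in ND tumors (1.42 ± 0.21, adjusted p = 0.00123), and Acadm at 108 ± 21 TPM and 58.4 ± 12.4 TPM (0.88 ± 0.21, adjusted p = 0.0144). Bdh1 (chromosome 16, 31422280 to 31458901) was at 300 ± 78 TPM and 80.6 ± 20.1 TPM (1.88 ± 0.31, adjusted p = 0.0021). Cyp4a14 (3.63 ± 0.65, adjusted p = 0.00307) and the P450 Cyp2e1 (3.17 ± 0.51, adjusted p = 0.00171) were among the largest rises under the naming rule, with Igfbp2 (3.10 ± 0.46, adjusted p = 0.00123). Nontumor liver in KD tumors was not excluded for Cyp4a14. The largest fall under that rule was that of Gstm3, from 162 ± 94 TPM on ND to 7.84 ± 3.64 TPM on KD (-4.08 ± 0.61, adjusted p = 0.00123). Next were Cbr3, a carbonyl reductase (-3.69 ± 0.39, adjusted p = 0.000283), and Gstp2 (-3.38 ± 0.54, adjusted p = 0.00177). Snord49a, a small nucleolar RNA, was at 1.87, 14.4, 14.4 and 10.8 TPM in KD tumors and was listed at 0 in all 4 ND tumors.

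A total of 113 genes differed between KD and ND tumors on the deposited scale, of which 39 (34.5%) were higher and 74 lower on KD. After rescaling there were 2126, of which 961 (45.2%) were higher and 1165 lower, and 102 genes were called in the same direction on both scales, none in opposite directions. Scaling the listed genes of each library to 1 common sum instead gave 2868 genes, of which 276 were higher and 2592 lower, so the balance of directions rests on the scaling. Leaving ND nontumor 4 out of the shared fit gave 1599 genes (745 higher, 854 lower) on the deposited scale and 2166 (980 higher, 1186 lower) after rescaling. Of 121 named genes that passed, 19 also passed on the deposited scale, and none changed direction. The groups did not overlap in 22.9% of tested genes (chance 2.9%). The deposited count was 68 without KD tumor 4 and 175 without ND tumor 4. The rescaled count was 1409, 1045 and 1115 without KD tumors 2, 3 and 4 and 1156 without ND tumor 1. The listed TPM share separated the tumor groups (77.05% to 79.93% on KD, 49.96% to 66.48% on ND). The log2 fold changes after rescaling correlated across genes with transcript length (Spearman's rho -0.189) and GC content (-0.194). After each library was adjusted for its length and GC trends, 1972 genes passed, and 1606 (75.5%) of the 2126 still passed in the same direction.

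**Figure D3:**
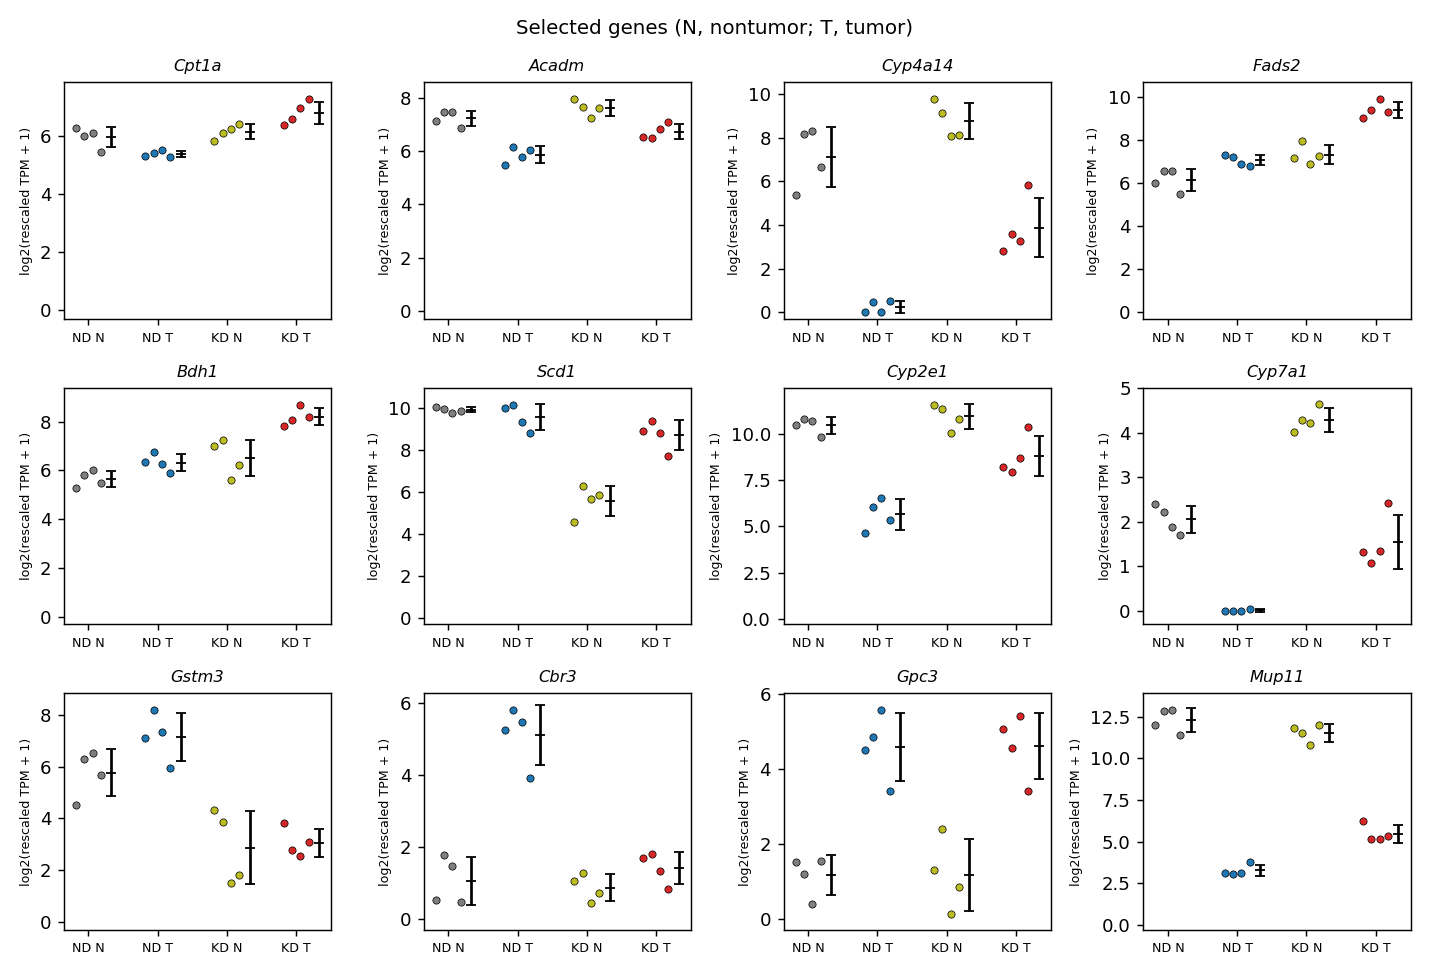
Rescaled log2(TPM + 1) of 12 genes (vertical axes) in the 4 groups, with 1 point per library and bars for mean ± SD (n = 4). Cpt1a, Acadm, Fads2 and Bdh1 are higher in KD than in ND tumors, Gstm3 and Cbr3 are lower, and Scd1 is lowest in KD nontumor liver.

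The fatty acid degradation list was higher on KD in tumor, with 22 of 43 members rising, none falling and 21 not passing (30 rose within the list; median 0.88, adjusted p = 1.55e-10, and adjusted p = 0.677 with an estimated correlation). On the deposited scale 1 member passed, and after length and GC adjustment 23 did (median 0.83). Aldh3a2 (2.05 ± 0.28), a fatty aldehyde dehydrogenase, and the peroxisomal enzyme Ehhadh (1.56 ± 0.45) were among those that rose. Ketone body genes rose in 5 of 9 cases (5 within the list; median 1.05, adjusted p = 0.000546, and adjusted p = 0.468 with an estimated correlation). PPAR alpha targets rose in 13 of 28 cases (15 within the list; median 0.77, adjusted p = 2.4e-07, and adjusted p = 0.683 with an estimated correlation). Examples were the fatty acid carrier Fabp1 (2.50 ± 0.59) and the lipid droplet gene Cidec (1.80 ± 0.45). Ppara (0.28 ± 0.29, adjusted p = 0.531), Pdk4 (0.37 ± 0.38, adjusted p = 0.535) and Fgf21 (0.32 ± 0.27, adjusted p = 0.431) did not pass. Peroxisome biogenesis (3 of 16 rose, 4 within the list; adjusted p = 0.0374, and adjusted p = 0.797 with an estimated correlation) passed after rescaling but not on the deposited scale. Lipogenesis was higher (5 of 22 rose, 5 within the list; adjusted p = 0.0424, and adjusted p = 0.797 with an estimated correlation). So was cholesterol synthesis (6 of 24 rose, 6 within the list; adjusted p = 0.000293, and adjusted p = 0.797 with an estimated correlation). The desaturases of polyunsaturated fat, Fads2 (2.34 ± 0.27) and Fads1 (1.68 ± 0.25), rose. Fasn (0.17 ± 0.39, adjusted p = 0.796) and Scd1 (-0.88 ± 0.39, adjusted p = 0.127) did not pass.

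Oxidative phosphorylation genes rose in 19 of 42 cases (34 within the list; median 1.00, adjusted p = 2.73e-12, and adjusted p = 0.797 with an estimated correlation). Examples were Cox6a1 (1.87 ± 0.58) and Uqcrc2 (1.53 ± 0.34). After length and GC adjustment 17 passed (median 0.78). Tricarboxylic acid cycle genes rose in 11 of 21 cases (16 higher and 1 lower within the list; median 0.68, adjusted p = 1.27e-06, and adjusted p = 0.683 with an estimated correlation). After that adjustment 9 passed (median 0.55). Ribosomal protein genes were higher as a list (median 0.70, adjusted p = 1.28e-09, and adjusted p = 0.797 with an estimated correlation). Of 56 members 3 rose, none within the list, and the median was 0.62 after adjustment. MYC targets rose in 4 of 40 cases and fell in 2 (10 and 2 within the list; adjusted p = 0.0106, and adjusted p = 0.852 with an estimated correlation). Unfolded protein response genes rose in 2 of 22 cases (2 within the list; adjusted p = 0.00692, and adjusted p = 0.797 with an estimated correlation). In glycolysis 3 rose and 5 fell of 25 (3 and 6 within the list; adjusted p = 0.378). Ldha rose (1.57 ± 0.29), and Pkm fell from 36.3 ± 24.3 TPM on ND to 12 ± 4.9 TPM on KD (-1.41 ± 0.38).

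Pericentral genes rose in 13 of 21 cases (15 within the list; median 1.16, adjusted p = 5.64e-09, and adjusted p = 0.421 with an estimated correlation). Examples were Rgn (2.69 ± 0.42) and Oat (2.50 ± 0.43), and the median was 1.19 after length and GC adjustment. P450 and drug metabolism genes rose in 12 of 41 cases (15 within the list; adjusted p = 9.24e-05, and adjusted p = 0.797 with an estimated correlation). Male-biased genes rose in 6 of 23 cases (13 within the list; adjusted p = 8.24e-07, and adjusted p = 0.683 with an estimated correlation). After that adjustment 5 passed (median 0.67, against 1.06 before), with nontumor liver not excluded for some Mup members. Secreted proteins rose in 6 of 38 cases and fell in 2 (6 and 2 within the list; adjusted p = 9.24e-05, and adjusted p = 0.797 with an estimated correlation), the lipoprotein gene Apoa5 by 2.02 ± 0.28. Cyp7a1, listed at 0 in 3 ND tumors and at 0.033 TPM in ND tumor 4, was at 1.12 to 4.36 TPM in the KD tumors. The bile acid list did not pass (4 of 17 rose, 4 within the list; adjusted p = 0.0794). Neither did periportal genes (1 rose and 1 fell of 19; adjusted p = 0.342), hepatocyte transcription factors (4 rose and 1 fell of 18; adjusted p = 0.142) or gluconeogenesis (1 of 13 rose; adjusted p = 0.483), with the same counts within the list. Targets of NRF2, the regulator of antioxidant and glutathione genes, fell in 7 of 23 cases (10 lower and 1 higher within the list; median -0.63, adjusted p = 0.00692, and adjusted p = 0.797 with an estimated correlation). Gstm1 (-2.64 ± 0.47) and Nqo1 (-1.74 ± 0.46) were among the 7, with Gstm3 and Cbr3. After length and GC adjustment 8 passed (median -0.60).

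Endothelial markers moved in both directions, 5 of 25 rising and 9 falling (7 and 10 within the list; adjusted p = 0.481). Clec4g, a marker of sinusoidal endothelium, rose (2.40 ± 0.32), and the vascular markers Pecam1 (-1.74 ± 0.24), Cd34 (-1.87 ± 0.26) and Cdh5 (-1.28 ± 0.26) fell. The Kupffer cell gene Cd5l rose (1.72 ± 0.40), and the T cell genes Lck (-1.49 ± 0.41) and Lag3 (-1.11 ± 0.36) fell. Their lists did not pass (adjusted p = 0.342 and adjusted p = 0.099). Neither did mitotic genes (adjusted p = 0.594), S phase (adjusted p = 0.483), cancer and fetal markers (median 0.02, mean -0.06, adjusted p = 0.483), or RAS and ERK output (adjusted p = 0.594). Nor did the integrated stress response (adjusted p = 0.628), interferon response (adjusted p = 0.285), hypoxia (adjusted p = 0.179), monocytes and macrophages (median -0.06, mean 0.02, adjusted p = 0.972), stellate cells (adjusted p = 0.762), red blood cells (adjusted p = 0.483) or urea cycle genes (adjusted p = 0.13). Mki67 (-0.42 ± 0.39, adjusted p = 0.478), Afp (1.20 ± 0.83, adjusted p = 0.33), Gpc3 (0.03 ± 0.52, adjusted p = 0.975), Nras (-0.03 ± 0.15, adjusted p = 0.91) and Myc (-0.86 ± 0.40, adjusted p = 0.142) did not pass. With deposited values bile acid (adjusted p = 0.0224), hypoxia (adjusted p = 0.0494), T and NK cell (adjusted p = 0.0121) and neutrophil genes (adjusted p = 0.00405) passed as well, though none did with an estimated correlation. Of the 16 lists that passed after rescaling, 5 had members that passed with deposited values. These were 1 in fatty acid degradation, 1 PPAR alpha target, 2 P450 and drug metabolism and 2 pericentral genes, all higher, and 3 NRF2 targets, all lower. In the other 11, oxidative phosphorylation, the tricarboxylic acid cycle and male-biased genes included, none passed. Scores of the 16 lists did not overlap between the diets except for cholesterol synthesis, P450 and drug metabolism, and MYC targets. For MYC targets KD tumors 1 and 2 (4.267 and 4.222) lay within the ND range (4.08 to 4.287), so the difference rests on KD tumors 3 and 4 (4.774 and 4.72).

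**Figure D4:**
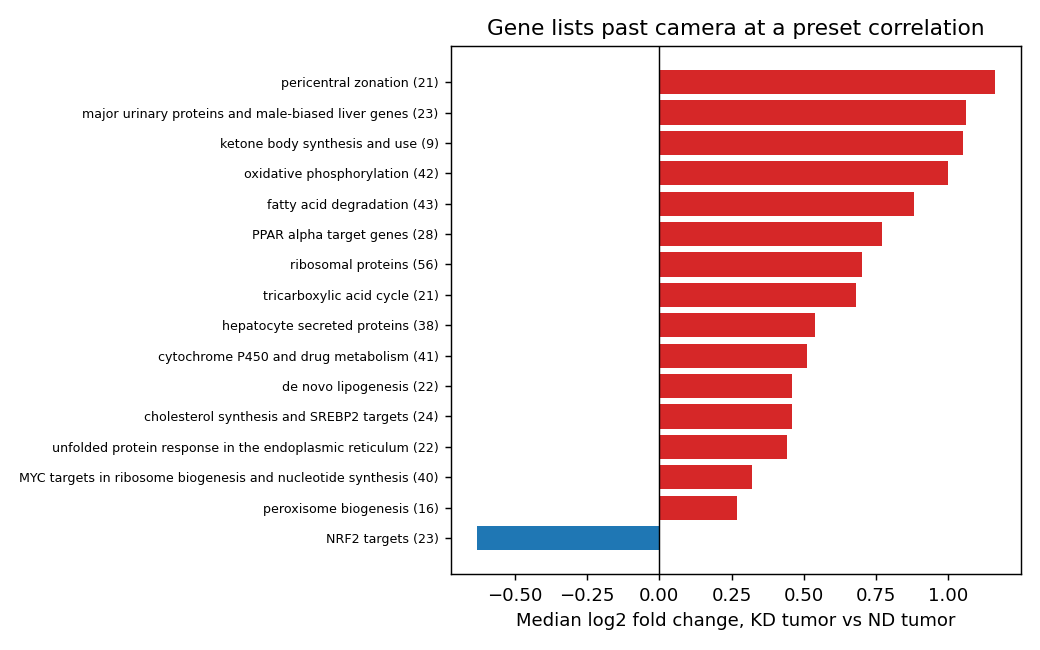
Median log2 fold change, KD against ND tumor after rescaling (horizontal axis), of the 16 gene lists that passed the camera test with a preset correlation of 0.01, one bar per list, starting at 0. Oxidative phosphorylation (1.00), fatty acid degradation (0.88) and pericentral genes (1.16) are higher, and NRF2 targets (-0.63) are lower; none of the 16 passed with an estimated correlation.

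The fatty acid degradation score, the mean log2(TPM + 1) of the 43 tested genes in a library, was 6.57 ± 0.17 in KD nontumor, 5.74 ± 0.30 in KD tumor, 5.41 ± 1.65 in ND nontumor and 4.86 ± 0.23 in ND tumor (deposited, SD, n = 4). After rescaling it was 6.17 ± 0.28, 5.65 ± 0.29, 5.88 ± 0.34 and 4.75 ± 0.14. KD tumors exceeded ND tumors by 0.874 (exact permutation p = 0.0286) and by 0.903 after rescaling (exact p = 0.0286), where 0.0286 is the smallest p that the 70 assignments allow. The tumors lay below nontumor liver by -0.546 on ND (exact p = 0.6571) and -0.837 on KD (exact p = 0.0286) on the deposited scale. The differences were -1.137 (exact p = 0.0286) and -0.516 (exact p = 0.0857) after rescaling. In nontumor liver KD exceeded ND by 1.166 (exact p = 0.0286) on the deposited scale and 0.282 (exact p = 0.2286) after rescaling. Without ND nontumor 4, whose deposited score was 2.94, the deposited differences were -1.368 (exact p = 0.0286) for ND tumor against nontumor and 0.343 (exact p = 0.0571) for the diets in nontumor liver. The diet effect in tumor did not differ detectably from that in nontumor liver (-0.291, exact p = 0.9249 deposited, and 0.62, exact p = 0.1645 rescaled, over 4900 assignments).

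**Figure D5:**
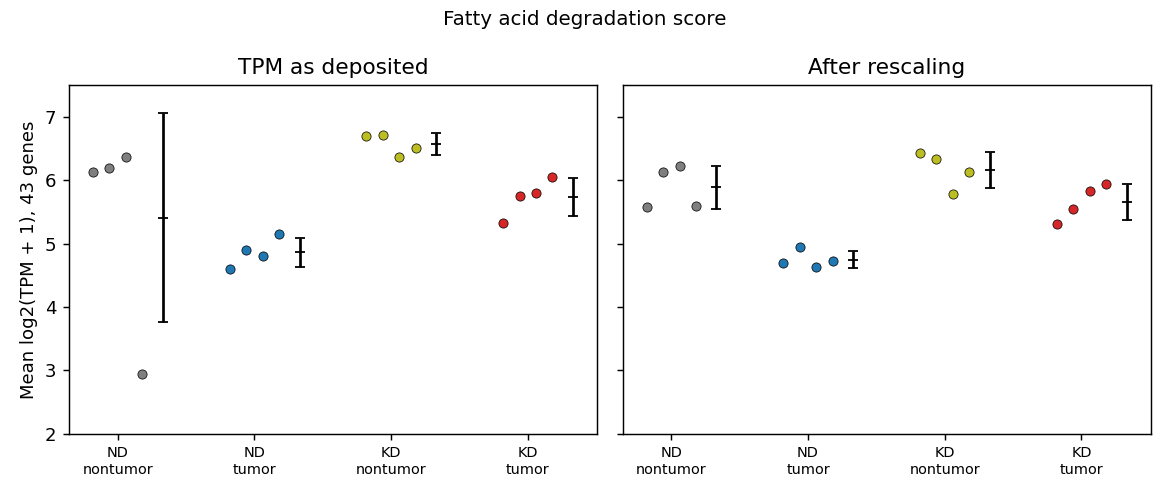
Fatty acid degradation score (mean log2(TPM + 1) of 43 genes, vertical axis from 2) per library on the deposited and the rescaled scale, with group mean and SD (n = 4). The deposited score of ND nontumor 4 lies at 2.94, and on both scales every KD tumor lies above every ND tumor.

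In nontumor liver the diets differed in few genes. Scd1 was at 51.4 ± 22.1 TPM on KD and 975 ± 80 TPM on ND (-4.34 ± 0.39, adjusted p = 6.26e-05). Cyp7a1 (chromosome 4, 6265612 to 6275633) was at 18.7 ± 3.7 TPM and 3.23 ± 0.90 TPM (2.23 ± 0.25, adjusted p = 0.000579). Lower on KD were also Cyp2c69 (-3.58 ± 0.41, adjusted p = 0.000579), Ugt2b37 (-1.80 ± 0.31, adjusted p = 0.0474), and Tbc1d8 (-1.62 ± 0.23, adjusted p = 0.00544). So were Atg16l2 (-1.40 ± 0.18, adjusted p = 0.00174) and Gm11827 (-1.46 ± 0.25, adjusted p = 0.0474), a predicted gene named after its values were seen. These 7 genes (1 higher, 6 lower) were all that limma called after rescaling, with 1191 at an unadjusted p under 0.05. With deposited values 65 genes passed, of which 60 (92.3%) were higher and 5 lower on KD, 3 of them shared with the rescaled calls. Without ND nontumor 4 the deposited scale gave 7 genes (3 higher, 4 lower) and the rescaled values 11 (4 higher, 7 lower), and without KD nontumor 4 the rescaled count was 12. The groups did not overlap in 5.9% of tested genes (chance 2.9%). Of the oxidation and ketone genes, Cpt1a (0.18 ± 0.21, adjusted p = 0.874), Acadm (0.39 ± 0.21, adjusted p = 0.654), Bdh1 (0.86 ± 0.31, adjusted p = 0.38) and Cyp4a14 (1.66 ± 0.65, adjusted p = 0.438) did not pass.

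Among gene lists in nontumor liver, cholesterol synthesis genes were higher on KD (median 0.57, adjusted p = 7.92e-10, and adjusted p = 0.38 with an estimated correlation). None of the 24 passed over all genes, and 11 rose within the list. The fatty acid degradation list was higher by a median of 0.28 (3 higher and 1 lower within the list, none over all genes; adjusted p = 0.000345, and adjusted p = 0.755 with an estimated correlation). PPAR alpha targets were higher by 0.29 (3 within the list, none over all genes; adjusted p = 0.00243, and adjusted p = 0.757 with an estimated correlation). Hepatocyte transcription factors were higher (median 0.44, 8 within the list, none over all genes; adjusted p = 2.36e-07, and adjusted p = 0.162 with an estimated correlation). So were clock genes (median 0.38, 4 within the list, none over all genes; adjusted p = 0.000209, and adjusted p = 0.38 with an estimated correlation). Unfolded protein response genes were lower (median -0.56, 6 lower within the list, none over all genes; adjusted p = 1.58e-09, and adjusted p = 0.38 with an estimated correlation). NRF2 targets were lower too (median -0.30, 3 within the list, none over all genes; adjusted p = 0.000345, and adjusted p = 0.718 with an estimated correlation). Also higher as lists were female-biased genes (median 0.78, adjusted p = 0.000313, and adjusted p = 0.38 with an estimated correlation) and the tricarboxylic acid cycle (median 0.24, adjusted p = 0.00672, and adjusted p = 0.757 with an estimated correlation). Immediate early genes were higher (median 0.32, adjusted p = 0.0226, and adjusted p = 0.881 with an estimated correlation). Markers of red blood cells (median -0.82, adjusted p = 0.000376), Kupffer cells (median -0.50, adjusted p = 4.86e-05), stellate cells (median -0.41, adjusted p = 0.000345), B cells (median -0.46, adjusted p = 0.0353) and monocytes and macrophages (median -0.32, adjusted p = 0.00314) were lower. In the same order, adjusted p = 0.38, 0.38, 0.718, 0.718 and 0.718 with an estimated correlation. Male-biased genes (median -0.40, adjusted p = 0.00243, and adjusted p = 0.757 with an estimated correlation) and secreted proteins (median -0.22, adjusted p = 0.00243, and adjusted p = 0.817 with an estimated correlation) were lower. No member of these 10 lists passed over all genes, and within the list 2 female-biased genes were higher and 1 red blood cell gene lower. Ketone body genes (adjusted p = 0.381), oxidative phosphorylation (adjusted p = 0.235), lipogenesis (median 0.00, mean -0.14, adjusted p = 0.955) and ribosomal proteins (adjusted p = 0.0902) did not pass. With deposited values the secreted protein list did not pass (adjusted p = 0.745). Bile acid (adjusted p = 0.0154) and oxidative phosphorylation genes (adjusted p = 0.0177) were then higher as lists, and mitotic (adjusted p = 0.00299) and T and NK cell genes (adjusted p = 0.000113) lower, none of them with an estimated correlation. In the lists that passed after rescaling, the single members that passed on that scale, all higher, were 2 each in the fatty acid degradation, PPAR alpha, hepatocyte transcription factor, female-biased and clock lists and 1 immediate early gene. In other lists named here 1 bile acid gene was higher and 1 lipogenesis gene lower.

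Scores overlapped between the diets for 16 of the 17 lists that passed, all but hepatocyte transcription factors. The differences of unfolded protein response genes (6.517 and 6.395 in KD nontumor 1 and 2, 5.576 and 5.672 in KD nontumor 3 and 4, and 6.283 to 6.81 on ND), clock genes (3.667 and 3.644, 4.246 and 4.258, and 3.311 to 3.735), NRF2 targets, secreted proteins, and monocytes and macrophages rest mainly on KD nontumor 3 and 4. Those of fatty acid degradation (6.42 and 6.336, 5.784 and 6.122, and 5.582 to 6.227), female-biased genes (2.176 and 3.256, 1.531 and 1.528, and 0.921 to 1.676), PPAR alpha targets and immediate early genes rest mainly on KD nontumor 1 and 2. Those of stellate cells (3.328 and 3.269, against 2.687 and 2.669 in ND nontumor 2 and 3) and B cells (3.234 and 3.167, against 2.438 and 2.374) rest mainly on ND nontumor 1 and 4. That of male-biased genes rests on ND nontumor 2 and 3 (9.138 and 9.22, against 8.178 and 7.269 in ND nontumor 1 and 4).

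The change from nontumor to tumor differed between the diets for single genes. The log2 fold change of Scd1 was 3.12 on KD and -0.34 on ND, a difference of 3.46 ± 0.55 (adjusted p = 0.0175). Lhpp, a phosphatase, fell by less on KD (-1.43 against -4.23, difference 2.81 ± 0.40, adjusted p = 0.0139). So did Mup11 (-6.06 against -9.02, difference 2.96 ± 0.50, adjusted p = 0.022), with nontumor liver in KD tumors not excluded. Gulo fell on ND (-2.35) and did not pass on KD (-0.50), a difference of 1.85 ± 0.29 (adjusted p = 0.0175). Cbr3 rose on ND (4.05) and did not pass on KD (0.54), a difference of -3.50 ± 0.55 (adjusted p = 0.0175). Cyp17a1 rose by less on KD (0.73 against 2.38, difference -1.65 ± 0.24, adjusted p = 0.0139). In deposited values 14 genes had such a difference, 2 (14.3%) higher and 12 lower, and after rescaling 82, of which 27 (32.9%) were higher and 55 lower, with 5 genes called on both. Without ND nontumor 4 the counts were 129 (29 higher, 100 lower) and 187 (60 higher, 127 lower). Left out 1 at a time, most libraries moved the deposited count by over 1.5 times. It was 27, 25, 31 and 29 without KD nontumor 1 to 4, and 27 and 37 without KD tumors 1 and 2. It was 41, 5 and 22 without ND nontumor 1 to 3, and 34, 36, 54 and 34 without ND tumors 1 to 4. The rescaled count was 51, 18 and 19 without KD nontumor 2 to 4, 35, 25 and 16 without KD tumors 2 to 4, 47, 9 and 14 without ND nontumor 1 to 3, and 13 without ND tumor 1.

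The diet effects in tumor and in nontumor liver were weakly alike across genes, which are not independent replicates. Pearson's r was 0.222, Spearman's rho 0.198 and the covariance 0.057 on the deposited scale, and 0.212, 0.197 and 0.048 after rescaling. With samples split by replicate number, so that no number entered both tissues, r was -0.049 and 0.323 (-0.041 and 0.334 after rescaling). The numbers are not known to mark mice, so this split may not keep the tissues of 1 mouse apart. After rescaling 1 gene was higher on KD in both tissues, where independent lists share 0.1, and 2 were lower in both, against 0.5.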

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

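A library was marked where its gap to the nearest of the other 3 in its group exceeded Dixon's 95% critical share of the group's range, and 16 of 288 groups over 72 measures were marked, where chance marks about 1 in 20, or 14.4. All tests of explanations were chosen after the results were seen.

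ND nontumor 4 stood apart in the listed TPM share (7.38%, others 73.36% to 84.29%), genes with TPM of at least 1 (6294, others 12034 to 12986), the Lars2 share of listed TPM (2.862%, others 0.019% to 0.073%), the deposited fatty acid degradation score (2.94, others 6.13 to 6.364), and the rescaled scores of female-biased genes (1.676, others 0.921 to 1.048) and hepatocyte transcription factors (4.727, others 4.92 to 4.943). Other marked values were the share of the 10 most abundant genes in ND tumor 2 (29.24%, others 21.55% to 22.52%), and the rescaled scores of bile acid genes in ND tumor 2 (5.006, others 4.619 to 4.667), hypoxia in ND tumor 4 (4.847, others 3.598 to 3.788), red blood cells in ND tumor 4 (4.3, others 3.27 to 3.329), peroxisome biogenesis in KD nontumor 2 (4.167, others 4.315 to 4.332), and muscle and gut genes in KD tumor 2 (3.505, others 3.691 to 3.702). Single genes marked on the rescaled log2 scale were Alb in KD tumor 1 (16.32, others 15.968 to 16.002), Cyp7a1 in ND tumor 4 (0.046, others 0) and Mki67 in KD nontumor 2 (2.761, others 1.117 to 1.383).

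The change from nontumor to tumor differed between the diets, by the interaction in limma after rescaling, for 11 named genes. The difference in log2 fold change was 2.81 for Lhpp, 1.85 for Gulo, 3.46 for Scd1, 3.5 for Cyp2c69, 1.77 for Ehd3 and 2.96 for Mup11. It was -1.94 for Rhbdl2 (listed at 0 in ND nontumor liver), -1.65 for Cyp17a1, -1.89 for Asap3, -3.5 for Cbr3 and -1.86 for Kyat1. On the deposited scale 1 of these, Cbr3, passed. Of gene lists, 18 differed by the same interaction, with medians of 0.57 for fatty acid degradation, 0.85 for ketone bodies, 0.42 for PPAR alpha targets, 0.65 for lipogenesis, 0.25 for urea cycle and amino acid genes, 0.36 for the tricarboxylic acid cycle, 0.97 for oxidative phosphorylation, 0.28 for P450 and drug metabolism, 0.82 for secreted proteins, 1.53 for male-biased genes, 1.31 for pericentral genes, 0.25 for MYC targets, 0.86 for ribosomal proteins, 0.96 for the unfolded protein response, 0.88 for B cells, 0.65 for Kupffer cells, 1.58 for red blood cells and -0.91 for female-biased genes. With an estimated correlation none of the 18 passed (adjusted p from 0.221 to 0.85). Some of these differences, as for oxidative phosphorylation and secreted proteins, rest in part on KD nontumor 3 and 4, whose scores are given above. For some Mup genes of the male-biased list, nontumor liver in KD tumors was not excluded.

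The listed share of ND nontumor 4 (7.38%) was weighed against transcripts outside the listed genes and against low depth. Lars2, a gene whose locus can take up reads of ribosomal RNA, held 2.862% of its listed TPM against at most 0.133% in the other 15 libraries, so unlisted RNA such as ribosomal RNA remained possible. Its listed reads were 0.63 times those of the next lowest library while its share was 0.148 times the next lowest, so low depth alone was excluded as the cause. The origin of the unlisted RNA remained open, and no biological explanation was tested.

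After rescaling 2126 genes differed between KD and ND tumors. Diet, length and GC trends, nontumor liver in KD tumors or library composition could be the cause. After the length and GC adjustment 75.5% (1606) passed in the same direction, which excluded those trends as the whole cause. For 99.6% of the 961 higher genes the rise needed more nontumor liver than the 4.89% that the 10 most depleted abundant genes allow. This excluded nontumor liver as the main cause, but not for those 10, Cyp4a14, Mup11 and Mup7 among them. The listed TPM share of the lowest KD tumor exceeded that of the highest ND tumor by 10.57 percentage points, so library composition and diet could not be told apart. RNA quality beyond length and GC remained open.

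In nontumor liver a split across the diets, KD nontumor 1 and 2 with ND nontumor 2 and 3 against the rest, gave 1164 genes after rescaling, where the diets gave 7. It gave 814 genes after the length and GC adjustment and 1099 with reads thinned to 3.42e6, so these trends and depth were excluded as the whole cause. Tumor shares were estimated, perhaps low, at 1.54%, 6.1%, 0.08% and 1.04% in KD nontumor 1 to 4 and 0.26%, 0.21%, 0.86% and 2.68% in ND nontumor 1 to 4. The median of the 1164 genes needed 111% tumor on the first side, and all needed more than the 12.4% that the 10 abundant genes most raised in tumor allow there, which excluded tumor cells as the main cause. A smaller contribution stayed possible, also to the female-biased genes, whose nontumor score was highest in KD nontumor 2 (3.256) and KD nontumor 1 (2.176). The circadian gene Dbp followed diet, not the split. It was at 23.4, 24, 70.9 and 100 TPM in KD and 17.2, 10.8, 5.6 and 5.2 in ND nontumor 1 to 4. No biological explanation was tested, and the cause remained open.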

How the results depend on the processing

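The scaling by listed genes, the fits without ND nontumor 4 in the shared fit, the repeats on rescaled values, voom and the length and GC adjustment were chosen after results were seen. Of the named genes, lists and score differences, none that passed in either of the 2 fits compared took the opposite sign (0 reversed). Among those that passed in neither, signs did differ, as for the score interaction (-0.291 deposited, 0.62 rescaled) and some lists between the 2 scales. The balance of the deposited counts moved too. On ND 77.2% of the called genes were higher in tumor, but 40% without ND nontumor 4 (median of all tested genes -0.11, against 0.42) and 44.2% with sample weights. For KD it was 34.8%, and 50.1% with rescaling. For the diets in tumor it was 34.5%, but 73% with a pseudocount of 0.1, 53.9% with sample weights, and 51.5% and 57.1% without KD tumor 4 and ND tumor 4. In nontumor liver it was 92.3%, but 14.3% with rescaling, 46.2% scaled to 1 common sum and 42.9% without ND nontumor 4. Of 198 values of gene counts 118 stayed within 1.5 times, of 9220 values of named genes 8254 kept their call (911 lost and 55 gained it), of 1125 values of gene lists 968 did (130 lost and 27 gained it), and of 92 score values 75 did. On the deposited scale 227 of 571 named gene results lost their call. The estimated correlation took the call from 105 of 225 list results, leaving 0 called lists in all 5 comparisons on the deposited scale and 1, 0, 0, 0 and 0 after rescaling. Where no cause follows from the setting itself, the cause was not tested.

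Deposited counts were, for tumor against nontumor on ND (1418), 3852 with rescaling, 3697 with the listed genes scaled to 1 common sum, 674 with only the groups compared and 4230 with sample weights, and 1076 to 3067 with 1 library left out. For KD (1111) they were 552 without a filter, 4360 with rescaling, 4027 scaled to that sum, 4627 with only the groups compared, 5367 with sample weights, 4451 without ND nontumor 4 in the shared fit, and 731 to 1127 with 1 library left out. For the diets in tumor (113) they were 31 without a filter, 2126 with rescaling, 2868 scaled to that sum, 1534 with only the groups compared, 2064 with sample weights, 1599 without ND nontumor 4 in the shared fit, and 68 to 175 with 1 library left out. In nontumor liver (65) they were 13 without a filter, 7 with rescaling, 13 scaled to that sum, 1297 with sample weights, and 7 to 83 with 1 library left out. For the interaction (14) they were 5 with a pseudocount of 0.1, 2 without a filter, 82 with rescaling, 536 scaled to that sum, 878 with sample weights, and 5 to 129 with 1 library left out.

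Rescaled counts were 2069, 2143 and 861 with a log2 fold change of at least 1 for tumor against nontumor on ND and KD and for the diets in tumor. In nontumor liver (7) they were 4 with a pseudocount of 0.1, 13 scaled to that sum, 2 with only the groups compared, 432 with sample weights, 11 with the length and GC adjustment and 12 with its single pass. For the interaction (82) they were 32 without a filter, 536 scaled to that sum and 393 with sample weights. With 1 library left out they were 3086 to 3813, 3260 to 4506, 1045 to 1992, 5 to 12 and 9 to 187. With voom they were 3727, 4317, 2499, 6 and 81.

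Deviations of same-numbered tumor and nontumor samples correlated at -0.11, 0.14, -0.11 and -0.07 on ND and -0.01, 0.07, -0.04 and 0.16 on KD. Of 8 tumor samples, 1 correlated best with its own number. At n = 4 this cannot settle pairing. With the replicate block the deposited count in nontumor liver was 99, and rescaled counts were 1304 and 3 for the diets in tumor and nontumor liver and 33 for the interaction. With the number as a random replicate block deposited counts were 917 and 726 for tumor against nontumor on ND and KD and 1 for the interaction. With the replicate block and a sign-flip test, score differences of -0.837 (tumor against nontumor on KD), 0.874 and 1.166 (diets in tumor and nontumor liver) on the deposited scale and of -1.137 (ND) and 0.903 (diets in tumor) after rescaling had an exact p of 0.125, the smallest possible with 4 differences.

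With rescaling the score difference was -1.137 on ND (gained), -0.516 on KD (lost) and 0.282 for the diets in nontumor liver (lost). With 1 library left out, deposited differences were -1.368 to -0.227 on ND, -0.943 to -0.703 on KD, 0.769 to 1.009 for the diets in tumor (lost at 0.787, 0.884 and 0.856 without ND tumors 1, 2 and 3, exact p = 0.0571) and 0.343 to 1.485 in nontumor liver (lost at 1.122, 1.117, 1.234 and 1.189 without KD nontumor 1 to 4 and at 0.343 without ND nontumor 4).

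Of 35 splits of the same libraries, only the real one called as many genes as the real groups in the 4 deposited comparisons. The same held after rescaling except in nontumor liver, with 2 of 35. For the interaction it was 11 of 100 deposited and 4 of 100 rescaled. Chance was not excluded for rescaled nontumor liver or the interaction, whose splits mix in diet effects and cannot test it alone. The highest other deposited splits had 1396 (real 1418, with ND nontumor 4 on the side of the tumors), 132 (1111), 24 (113), 31 (65) and 82 genes (14) for tumor against nontumor on ND and KD, the diets in tumor and nontumor liver, and the interaction. After rescaling they had 11 (3852), 2 (4360), 8 (2126), 1164 (7) and 2064 genes (82). The last split kept the tumors by diet, and so their diet effect, and set KD nontumor 3 and 4 with ND nontumor 3 and 4. The 1164 genes, against 7, point to a structure among the nontumor libraries that does not follow diet.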

Other observations

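The delivered genes are human, and whether their reads count toward the listed mouse genes was not tested. Mouse Nras lay at 9.45 TPM in ND tumors and 7.62 TPM in ND nontumor liver. Mouse Myc lay at 5.40 TPM in KD tumors and 13.4 TPM in KD nontumor liver.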
